A study of Mus musculus with 12 samples.

How the data were processed

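Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for trimethylated lysine 9 of histone H3 (H3K9me3) was performed on mouse embryonic stem cells of 2 genotypes, Tex19.1+/- (heterozygous) and Tex19.1-/- (knockout). Per the labels, the cells came from the E14Tg2a line and were used at passages 12 to 20. Immunoprecipitated (IP) DNA and input DNA were each sequenced in 3 libraries per genotype, which gives 12 libraries. Per the labels' protocols, formaldehyde-fixed nuclei were sonicated, an Abcam antibody was used, libraries were made with a NEBNext Ultra kit and paired 75-nt reads were obtained on an Illumina HiSeq. Groups were taken from the titles. The genotype field of the labels contradicts the title in 6 of the 12 libraries, so the genotype of each library rests on the titles and source names. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so any spread between them may be technical. The deposited p-values behaved as counting error in the fit described below, so they may not measure even that spread.

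The submitters' processing notes name Bowtie2 2.2.6, HOMER 4.8, bedtools 2.25.0, edgeR with no version and the mouse build mm10, with no role or order. The data used here are the authors' deposited table of 1 comparison over 68291 regions. It holds for each region its coordinates, a log2 fold change, an average log2 CPM (read counts scaled to library size), a p-value and an adjusted p-value (FDR), per the file headers. Which of the 12 libraries entered it, whether input was used, how regions were defined and which genotype was the reference are not given in the sources used here. A comparison with groups in alphabetical order would make a positive value higher in knockout cells, but nothing states the order, so values are described by sign. The table has 0 columns of single libraries, so total reads per library and the spread between replicates were not analysed here. The CPM of all regions in the authors' deposited table sum to 1081650, so that the unit is close to a share of the reads inside the listed regions. Because values are relative within a library, a change common to all regions would not appear in them.

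The deposited FDR was checked against a Benjamini-Hochberg adjustment of the deposited p-values. The largest difference was 3.2e-05 and both gave the same 192 regions below 0.05. A region is called when its deposited FDR is below 0.05. A standard error was derived for each region as the absolute log2 fold change divided by the normal deviate of its 2-sided p-value, where that deviate was at least 1. This was possible for 19017 regions. Elsewhere the error was read from the median of regions of like log2 CPM. These derived errors inherit every assumption of the authors' test. A fit of the derived variance against 1/CPM above a log2 CPM of 4, over 6614 regions, left an intercept of -0.000176 (95% bootstrap interval -0.000231 to -0.000145, 200 resamples), so that the derived error fell with signal as counting error alone would, with no constant term for variation between libraries.

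Regions were set against the positions of 49997 genes of the RefSeq table of assembly GRCm38.p6, the assembly that mm10 names. This table gives gene bodies without exons, so exon and intron positions were not analysed here, nor were repeats. A region was assigned to a gene list when it lay in a member's body or within 5 kb of it. The 22 lists, the rule for named regions and the alternatives were written before the data were examined, and 7 lists of repeats were not analysed here. The planned tests needed values per library; the plan stated that a table of the authors' comparison alone would be described. Each list's median log2 fold change was set against 10000 random lists matched on log2 CPM in bins of 0.5, and gene lists also against lists moved together along the genome, which keeps neighbours together. Counts of calls were set only against the random lists, which draw regions singly and so may understate how often clustered calls arise. These list tests and the tests by position below replaced the planned ones after the data were seen. P-values of the 14 lists with at least 5 regions were adjusted by Benjamini-Hochberg. They treat regions, not cultures, as units and describe this 1 table.

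The rule for named regions took the 10 largest log2 fold changes per direction among called regions, up to 4 regions of smallest p per list, regions at the Tex19 genes and Ubr2, and the regions of highest signal. Its requirement that all libraries of 1 genotype lie on 1 side could not be applied. Other regions named were chosen after their values were seen. For shifts by position, each log2 fold change was taken relative to the median of regions of like log2 CPM outside chromosomes 11 and 16. Windows of 1 Mb with at least 8 regions were tested against their own chromosome's median with an exact signed-rank test, 2-sided, over 2422 windows. Adjacent windows with adjusted p below 0.01 and a shift of at least 0.25 were joined into blocks.

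The procedure was tested on a simulated table of the same 68291 regions. Chromosomes 11 and 16 were shifted by 0.3 in opposite directions, whereas both lay above the rest in the deposited data. A block was shifted by 0.5 and 200 regions above a log2 CPM of 4 were changed. Noise was drawn independently per region with the derived error, which also gave the p-values. Correlation between neighbours and spread beyond that error were not simulated, so recovery in the deposited data may be lower. Both chromosomes and 1 block were found. The shifts were returned as 0.29 on chromosome 11 and -0.30 on chromosome 16. Calls recovered 86% of regions changed by a log2 fold of 1 and 29% of those changed by 0.5, with 14 false calls among unchanged regions. The simulated shifts alone gave 113 calls, and 2 after their subtraction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives tried were a stricter FDR, the omission of the sex chromosomes or of short regions, and, added later, other adjustments, other errors, the removal of positional shifts and other gene extensions.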

Results

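H3K9me3, a histone mark of heterochromatin, was profiled in heterozygous and Tex19.1-/- mouse embryonic stem cells to ask where in the genome the mark differs when Tex19.1, a mammal-specific gene of germ cells and pluripotent cells, is missing. The series has 3 IP and 3 input libraries per genotype. The values analysed are those of the authors' deposited table, which compares the genotypes over 68291 regions and has no values of single libraries. The errors below are therefore derived from the authors' p-values, and the sign of a change is given as deposited, because the table does not state which genotype was the reference. These errors fell with signal as counting error alone would, so FDR values and calls may leave out variation between libraries.

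The regions covered 82.5 Mb of mm10, on 21 chromosomes and 29 unplaced scaffolds, with a median width of 773 bp. Of these, 24.7% overlapped a protein-coding gene, 10.9% overlapped another gene and 64.4% lay between genes. Signal was spread widely, and the strongest 1% of regions held 11.1% of the summed CPM. The median log2 fold change was -0.01, and 82.9% of regions lay within 0.5 of 0. Precision depended on signal. The derived standard error had a median of 0.48 at a log2 CPM of 2 to 3, 0.21 at 4 to 5 and 0.07 at 7 to 8. None of the 7513 regions below a log2 CPM of 2 was called, and the smallest called change was 1.51 at 2 to 3 and 0.24 at 7 to 8, so that smaller changes at weak regions were not detectable at this depth.

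No region lay within 5 kb of Tex19.1 (chromosome 11, 121146143 to 121148314), the nearest being 28126 bp away, so the table holds no value that checks the genotype labels at the targeted gene. Ubr2, a ubiquitin ligase that binds TEX19.1, also had no region within 5 kb. The region over Tex19.2, the neighbouring paralog (chromosome 11, 121116874 to 121118017), had a log2 fold change of 0.28 in the authors' deposited table, with a derived standard error of 0.30 and an FDR of 1.

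The 3 most negative changes among called regions lay at Impact and H13, members of the list of imprinted genes, which are expressed from the allele of 1 parent. The region in Impact (chromosome 18, 12972504 to 12974657) had a log2 fold change of -3.95 in the authors' deposited table (derived standard error 0.33, FDR 2.22e-28), which is a 15.5-fold difference. At H13, a gene that hosts the imprinted retrogene Mcts2, adjacent regions on chromosome 2 had -2.71 (152686848 to 152689238, derived standard error 0.25, FDR 1.53e-22) and -2.39 (152684939 to 152686186, derived standard error 0.38, FDR 7.97e-07) in the authors' deposited table. Smaller negative changes were called at other members. A broad region over the paternally expressed gene Mest (chromosome 6, 30733159 to 30741177) had -0.90 in the authors' deposited table, with a derived standard error of 0.08 and an FDR of 5.75e-24. Zfp787 (chromosome 7, 6130865 to 6135091) had -0.82 (FDR 8.94e-09) and the Gnas locus (chromosome 2, 174290250 to 174301263) -0.29 (FDR 0.00761) in the authors' deposited table. All of these regions overlap the gene body. The call at Gnas was lost under Holm adjustment and with the enlarged error described below.

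Of 43 imprinted genes in the list, 36 had a region. Of the list's regions, 6 were called, all negative. Random lists matched on signal had a mean of 1.24 calls, and 0.05% of them held as many. They drew regions singly, while 2 of the 6 calls were adjacent regions at H13, so the share of 0.05% may be too low. Adjusted over the list alone, 10 regions were called, 2 positive and 8 negative. The median of all regions of the list was -0.05, at percentile 15.0 of the random lists (adjusted p = 0.602, and adjusted p = 0.854 against lists moved along the genome). Among the 24 distinct strongest regions with at least 16 CPM, 5 were called negative, 0 were called positive and 19 were not called. Of the latter, 16 were negative and 3 positive, with values from -0.29 to 0.75, so that 21 of the 24 were negative. Strong regions outside the list were mostly negative too. Random lists of like signal, a comparison added after seeing the data, had a mean of 16.0 negative regions, and 1.99% held as many. Of the 22 regions outside the positional shifts described below, 19 were negative, against a mean of 16.4 in random lists drawn there, and 14.7% of those held as many. The regions left out there, on chromosome 11, lay at Zrsr1 and Commd1 (-0.29, derived standard error 0.11) and at Grb10 (-0.01). Both were below that chromosome's median of 0.28, so this omission takes out regions that are low for their chromosome. Relative to regions of like signal, with no chromosome median subtracted, 13 of the 24 were negative. In the authors' deposited table the regions at H19 (0.08, derived standard error 0.07), Igf2r and Airn (-0.02, derived standard error 0.08), Peg10 (-0.01, derived standard error 0.14) and Kcnq1ot1 (-0.07, derived standard error 0.12) each had an FDR of 1. The highest of them, at Zdbf2, had 0.75 with an FDR of 0.0705 in the authors' deposited table.

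**Figure D1:**
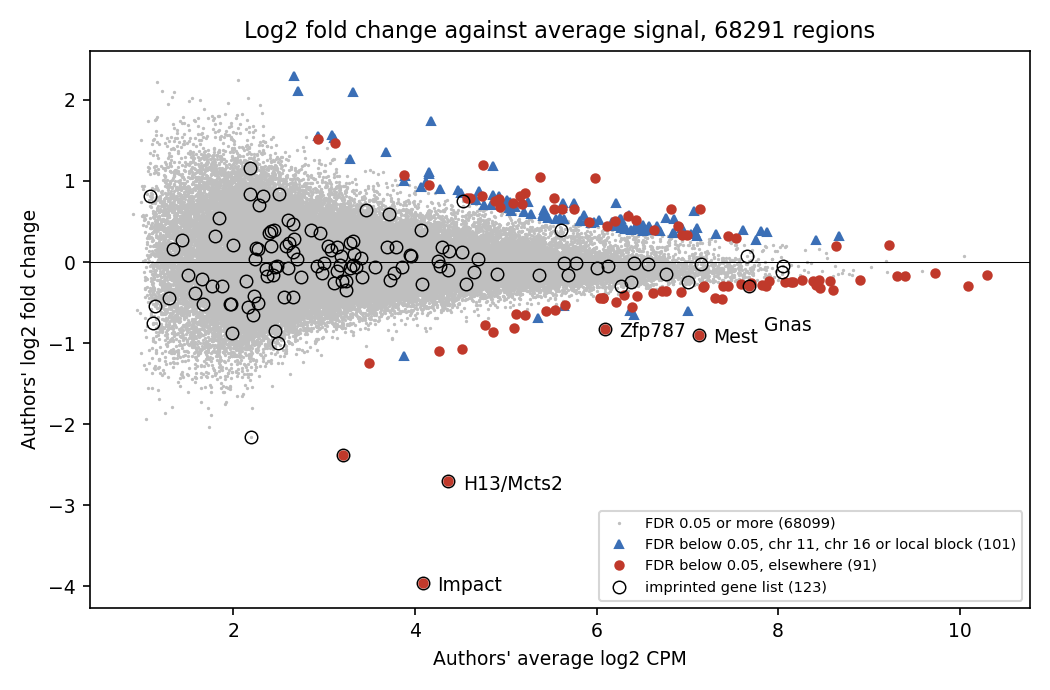
Each point is 1 region of the authors' deposited table, with its average log2 CPM on the x axis and its log2 fold change on the y axis. Triangles are called regions on chromosomes 11 and 16 or in a shifted block (101), filled circles are called regions elsewhere (91), and open circles mark the imprinted gene list, of which Impact at -3.95 and H13/Mcts2 at -2.71 lie farthest from 0.

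Across the genome 192 regions (0.281%) were called, 131 positive and 61 negative, and 101 remained at an FDR below 0.01. Outside the positional shifts described below, the larger share turned to negative, with 36 positive and 55 negative calls. The balance depends on the treatment of signal. With chromosome, block and like-signal medians subtracted, in a normal approximation, 74.7% of 75 calls were positive. An unadjusted p below 0.05 was found in 3239 regions, or 4.74%. Of the 192, 86 lay within 0.5 of 0, 106 reached 0.5 and 26 reached 1, and the median call was 0.59 among positive and -0.41 among negative ones. Outside these shifts, the positive changes of smallest p were in Fat1, an atypical cadherin (chromosome 8, 44948650 to 44955099), with 1.04 and an FDR of 1.21e-13 in the authors' deposited table, and in Prmt5, an arginine methyltransferase (chromosome 14, 54506315 to 54516080), with 0.65 and an FDR of 2.15e-12. A further region in Fat1 (45023892 to 45025101) had 1.51 with an FDR of 0.0448 in the authors' deposited table, a call that was lost in several alternatives, among them the omission of chromosomes 11 and 16 (adjusted p = 0.0671). On chromosome 4 the adjoining genes Noc2l and Samd11 shared a region at 1.04 (156244805 to 156249554, FDR 2.3e-08), and Six3os1, a noncoding RNA gene beside the homeobox gene Six3, had 1.19 (chromosome 17, 85611038 to 85613294, FDR 1.54e-06), both in the authors' deposited table. On the negative side, Zfp30 (chromosome 7, 29792034 to 29793960) had -1.08 with an FDR of 0.000278, and a region 7164 bp from Tmem196 (chromosome 12, 120028406 to 120029007) had -1.24 with an FDR of 0.0228 in the authors' deposited table. The call near Tmem196 was lost at an FDR below 0.01 and under Holm adjustment. The regions at Fat1 (smaller p), Prmt5, Noc2l and Six3os1 were chosen after their values were seen.

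The zinc finger list, taken by symbol and therefore not limited to genes with a KRAB domain, had 523 regions at 212 genes and 6 calls, 4 positive and 2 negative, against a random mean of 3.17, and 9.12% of random lists held as many. All 6 lay outside the positional shifts, where the random mean was 1.99 and 0.93% of random lists held as many, a share not adjusted for the number of lists. The called regions in the authors' deposited table include Zfp532 at 0.66 (FDR 1.19e-09), Zscan25 at 0.51 (FDR 0.00415), Zfp787 and Zfp30. Adjusted over the list alone, 7 were called. The olfactory receptor list had 515 regions and 1 call, near Olfr695, at 0.72 with an FDR of 0.00628 in the authors' deposited table; adjusted over the list alone it was also 1. The vomeronasal receptor list had 451 regions and 5 calls, 2 positive and 3 negative, against a random mean of 1.88, with as many in 3.62% of random lists and 8 adjusted over the list alone. Outside the positional shifts 2 calls were left, both negative, with as many in 26.5% of random lists. The count was 1 for gene bodies alone (random mean 0.53) and 9 with an extension of 10000 bp (random mean 2.90). Its called regions in the authors' deposited table include those near the pseudogenes Vmn2r-ps23 at -0.87 (FDR 0.00218) and Vmn1r-ps60 at -0.28 (FDR 0.000143). None of these lists had a median outside the random lists after adjustment (zinc finger 0.918, olfactory 0.324 and vomeronasal 0.324).

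Genes of pluripotency, differentiation and the germline held few regions and no calls. By the authors' FDR, 0 of 59 regions at germline and meiosis genes were called (2 with an unadjusted p below 0.05). The count was 0 of 40 at genes of the 2-cell stage (5) and 0 of 14 at H3K9 methylation factors (1). Clustered protocadherins had 0 of 20 (2) and histone genes taken by symbol 0 of 12 (2). Pluripotency genes had 0 of 5 (0), early lineage genes 0 of 6 (0) and fibroblast genes, a check for another cell type, 0 of 19 (2). Random lists matched on signal held a mean of 0.003 to 0.24 calls for these lists. For each list 0 calls was therefore the likely outcome and says little about its genes. With gene bodies alone, the 2-cell list had 10 regions and a median of -0.25 (adjusted p = 0.0594, and adjusted p = 0.18 against lists moved along the genome) in place of -0.02 over 40 regions. Adjusted over the list alone, the 2-cell list had 3 calls, all negative, the histone list 1, positive, and the other lists of this group 0. The histone list missed the H2ac and H2bc genes, and its regions of smallest p were at or near H1f7, H1f11-ps and H3f3a-ps2. Its positive call, in 4932438H23Rik on chromosome 16, had 0.62, or 0.27 with the chromosome median subtracted. It therefore does not describe the histone gene cluster. The test of the 8 medians of this group against matched random lists passed for none (adjusted p from 0.534 to 0.92). The region over Tcstv3, a 2-cell-stage gene (chromosome 13, 120317547 to 120321397), had -0.39 with an FDR of 0.0819 in the authors' deposited table. Regions near Nanog (0.08) and in Esrrb (-0.04 and 0.10), genes of the pluripotency network, each had an FDR of 1 in the authors' deposited table.

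Positive values were concentrated on chromosomes 11 and 16. Their median log2 fold changes were 0.28 and 0.32, against -0.18 to -0.0013 on the other chromosomes. Relative to regions of like signal elsewhere the medians were 0.31 and 0.35, or ratios of 1.24 and 1.27, and 84.5% (95% Wilson interval 83.2 to 85.7) and 86.3% (84.9 to 87.6) of their regions lay above the reference. Intervals treat regions as independent, which neighbours are not. These 2 chromosomes hold 8.43% of regions and 56.5% of the positive calls. Region-level positive changes there include Nrip1, a nuclear receptor corepressor (chromosome 16, 76320000 to 76321382), at 2.10 with an FDR of 8.31e-06, and a region 603 bp from the metalloproteinase gene Adamts1 (chromosome 16, 85803716 to 85804636) at 2.29 with an FDR of 0.00149 in the authors' deposited table. Both were weak regions, at 9.99 and 6.36 CPM, with derived standard errors of 0.35 and 0.47. With the chromosome median subtracted they had 1.75 and 1.95. The call near Adamts1 was lost under Holm adjustment (adjusted p = 0.0798). With a normal approximation and the error typical of each signal level, a test of another form than the authors', 122 positive and 57 negative regions were called. In that form, subtraction of chromosome and block medians gave 35 and 53, and of the median of like signal as well 56 and 19.

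**Figure D2:**
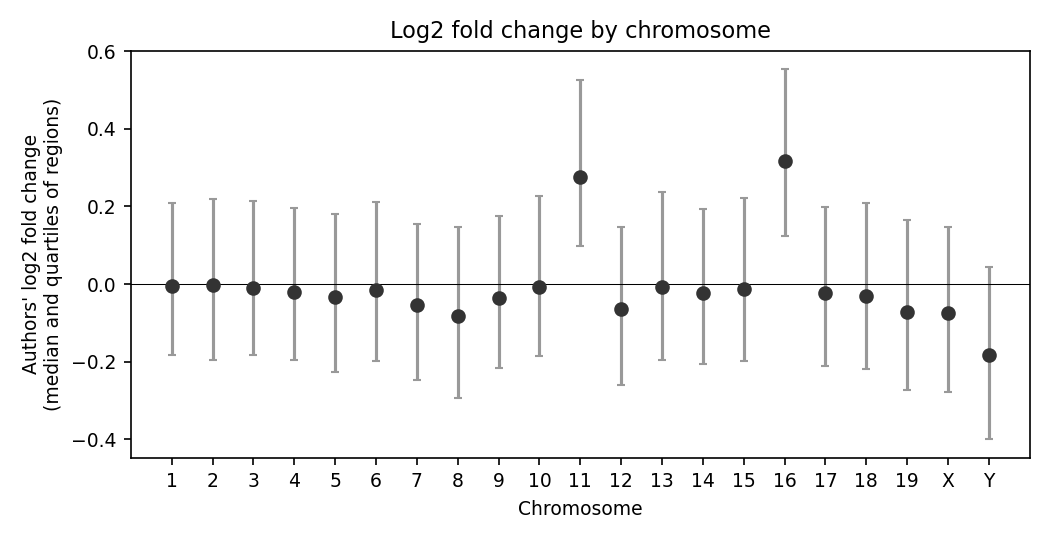
Median log2 fold change of the regions of each chromosome (points) with the quartiles of the regions (bars), from the authors' deposited table. Chromosomes 11 (0.28) and 16 (0.32) lie above the other chromosomes, whose medians run from -0.18 (Y) to -0.0013.

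Of the sex chromosome lists, the X chromosome had a median of -0.08 over 2552 regions, with 4 calls, all negative (1 adjusted over the list alone), and the Y chromosome -0.18 over 237 regions, with 0 calls and 6 unadjusted p-values below 0.05. Both medians were below all 10000 matched random lists (adjusted p = 0.0014, from the smallest p the random lists can give, 0.0002). These were 2 of the 14 lists tested, and none of the 12 gene lists had an adjusted p below 0.05. Low medians were not particular to X and Y. In a test added after seeing the data, with 1000 random lists per chromosome drawn outside chromosomes 11 and 16 and the shifted blocks, 4 of 17 autosomes also lay below their random lists at an adjusted p below 0.05, chromosome 8 at -0.08, chromosomes 19 and 12 at -0.07 and chromosome 7 at -0.05, and 6 lay above. X and Y were below here too. With lists drawn from all chromosomes, the raised ones included, 10 of 19 autosomes lay below.

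Of 2422 windows of 1 Mb, 23 had an adjusted p below 0.01. Of these, 15 had shifts under the size limit of 0.25, 14 negative and 1 positive relative to their own chromosome. They include chromosome 7 from 31 to 32 Mb (-0.16) and 33 to 34 Mb (-0.17) and chromosome 12 from 18 to 21 Mb. They also include chromosome 11 from 74 to 75 Mb (-0.17) and chromosome 16 from 3 to 4 Mb (-0.13). Those chromosomes were raised by 0.31 and 0.35, so these windows were low for their chromosome but not for the genome. The 8 windows beyond the limit made 4 blocks. On chromosome 13 from 22 to 26 Mb, a stretch with 34 protein-coding Vmn1r genes and 31 histone genes, linker histones included, 173 of 187 regions were positive, with a median of 0.49 and 18 positive calls. On chromosome 10 from 117 to 118 Mb, at Mdm2, the ubiquitin ligase of p53, and the lysozyme genes Lyz1 and Lyz2, 23 of 25 regions were negative, with a median of -0.57 and 2 negative calls. At the end of chromosome 16, from 97 to 99 Mb, where Dscam and Bace2 lie, 38 of 40 regions were negative, with a median of -0.47 and 3 negative calls, although the chromosome as a whole was positive. The window before it, from 96 to 97 Mb, did not pass the test but also had a negative median (-0.26, 23 regions), against 0.27 from 95 to 96 Mb, so negative medians began before 97 Mb. On chromosome 6 from 136 to 137 Mb, at Grin2b and Atf7ip, a cofactor of the H3K9 methyltransferase SETDB1, 40 of 48 regions were positive, with a median of 0.29 and 3 positive calls, and the windows on either side, which are not in the block, had 0.13 and 0.22. The largest adjusted p of a window in these blocks was 6.62e-05, 0.000168, 0.00407 and 0.000151 in that order (exact signed-rank test).

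**Figure D3:**
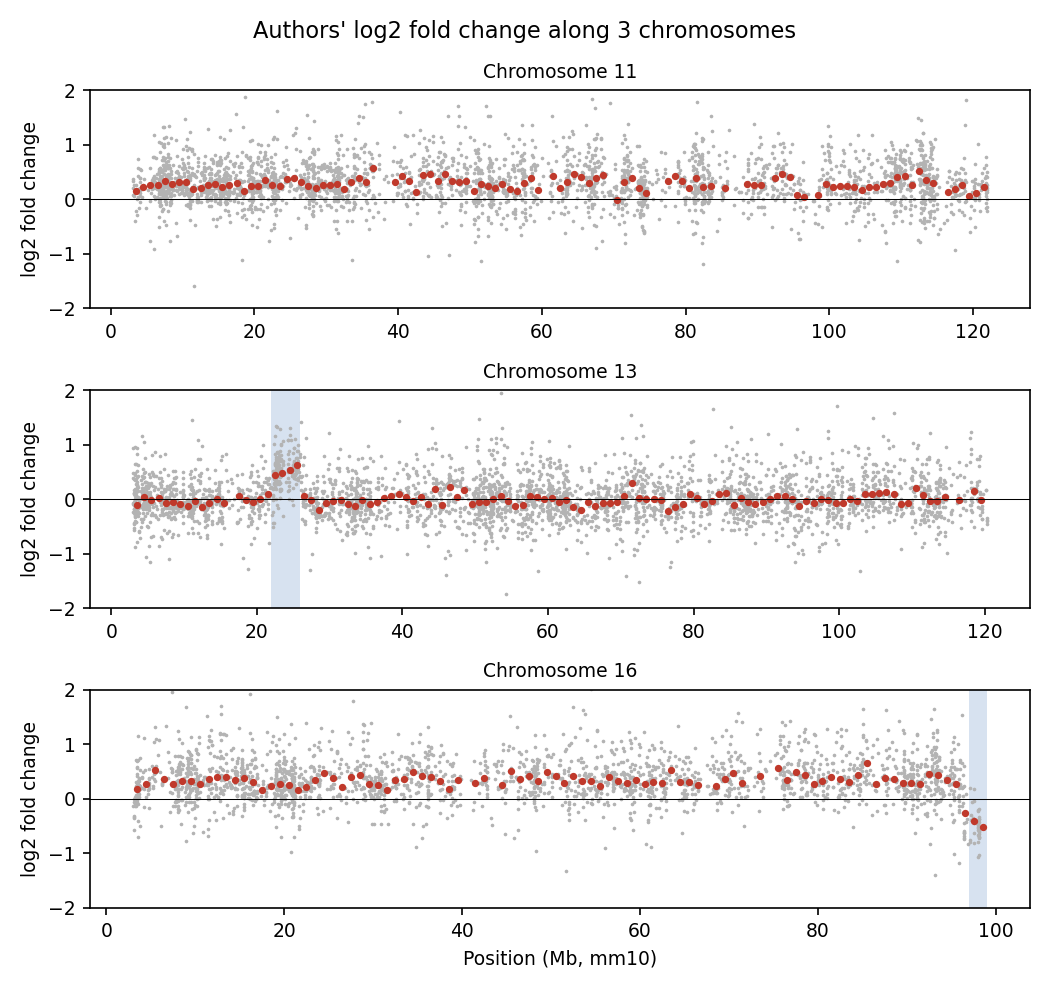
Log2 fold change of each region (grey points) from the authors' deposited table and medians of 1 Mb windows with at least 8 regions (red points), along chromosomes 11, 13 and 16 of mm10. Blue bands mark the blocks at 22 to 26 Mb of chromosome 13 (median 0.49) and 97 to 99 Mb of chromosome 16 (median -0.47), and 7 regions beyond 2 on the y axis are not shown.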

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

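Alternatives named as added were chosen after seeing the data. The 192 calls (131 positive, 61 negative) became 101 (67 and 34) at an FDR below 0.01, while 193 were found without chromosomes X and Y and 287 without regions shorter than 1000 bp. Among added alternatives, Holm adjustment gave 48 (30 and 18). The omission of chromosomes 11 and 16 gave 95 (49 positive), and that of the shifted blocks as well 70 (30 and 40). A normal approximation with the error typical of each signal level, in place of the authors' p-values, gave 179 (122 and 57), the value to set beside the next 3. In that form, an error enlarged by the extra spread of strong regions, 0.03 on the log2 scale, gave 108 (80 and 28) and by construction weighs most on strong regions. Subtraction of chromosome and block medians gave 88 (35 positive), and of the median of like signal as well 75 (56 and 19). The 56 calls of that last alternative shared with the original ones include 5 of the 6 at imprinted genes, and all 6 were called in the other alternatives except Holm adjustment and the enlarged error (5 each). Under Holm adjustment and the enlarged error the call lost was that at Gnas. Called regions within 1 Mb counted as 1 gave 111.

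With chromosome and block medians subtracted, regions inside the shifts changed sign: near 6720473M11Rik -0.020, Carmil1 -0.14, Dcdc2a -0.13, Vmn1r-ps123 -0.075 and Sfi1 -0.24, the last becoming a call. With the median of like signal subtracted too, Carmil1 had -0.037, Dcdc2a -0.031, the region near Gm31963 0.035 and 9630028I04Rik 0.066. The last, the strongest region, was set against only itself and Gm51701 (-0.30), so its change of sign comes from that pair. These reversals follow from the subtraction. Of the other values of named regions, 427 kept their sign and side of the threshold, 85 lost the call and 4 gained one. Signs could change only where medians were subtracted, and uncalled regions that stayed uncalled were not counted. The 427 therefore do not measure stability. The number of lists past 0.05 was 2 (X and Y) under each gene extension and without the shifts, although the 2-cell median moved from -0.02 to -0.25 with gene bodies alone (adjusted p = 0.0594, 10 regions), and 0 of the 12 gene lists passed against lists moved along the genome.

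No paired analysis was possible because the table has no values of single libraries. For the same reason other settings of normalization, low-count filter, pseudocount, other test, replicates left out in turn, groups from the genotype field, input, IP against input, their interaction, library shares, and gene set tests were not run, and other splits of the libraries could not be counted. Repeat lists were not analysed here, for lack of an annotation. Depth limits weak regions, as the derived errors show.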

Other observations

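Tests and regions in this part were chosen after the result was seen. Outside the shifted chromosomes and blocks, 7 windows of 1 Mb held at least 3 calls, against a mean of 0.95 when as many calls were drawn among regions of like signal there, and none of 10000 draws reached 7. In 3 of them, on chromosomes 1 (from 166 Mb), 5 (from 145 Mb) and 17 (from 27 Mb), the calls had both signs. In the others they had 1 sign. On chromosome 4 from 156 to 157 Mb, 3 positive calls lay in adjoining regions at Noc2l and Samd11 and at Agrn. Of these, 2 were called in a normal approximation with an error enlarged by the extra spread of strong regions (highest adjusted p 0.0532). On chromosome 2 from 131 to 132 Mb, 4 positive calls lay at 5330413P13Rik, Erv3 and the prion protein gene Prnp with its neighbour Prn, from 0.45 to 0.75 in the authors' deposited table. On chromosome 12 from 20 to 21 Mb, 6 negative calls ranged from -0.45 to -0.13 in the authors' deposited table, of which 5 were called without chromosomes 11 and 16, 4 with chromosome and block medians subtracted and 0 with an error enlarged by the extra spread of strong regions. At or beyond Asmt near the end of chromosome X, 3 negative calls ranged from -0.81 to -0.27 in the authors' deposited table. In each of these 3 alternatives only the region at -0.81 was called, and the others had adjusted p-values from 0.0524 to 0.149. The 4 calls at Prnp and its neighbours were called in all 3. Strong regions leaned negative. At a log2 CPM above 8, 20 of 58 regions were called, 16 negative and 4 positive, and the spread of regions outside the shifts was 2.12 times the derived error, against 0.88 times at a log2 CPM of 4 to 5. The strongest region, in 9630028I04Rik (chromosome 17, 27236789 to 27265362), had a log2 CPM of 10.3 and a log2 fold change of -0.16 with an FDR of 2.86e-05 in the authors' deposited table, and an adjusted p of 0.13 with the enlarged error. Outside the shifts, in the first 4 Mb of the autosomes and X, the end that carries the centromere in mouse, 8 of 972 regions were called, all negative. The other 60903 regions of these chromosomes had 46 negative and 35 positive calls. Relative to regions of like signal, the medians were -0.04 in the first 4 Mb and 0.0002 in the rest.

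Chromosomes 11 and 16 lay above the rest. Scaling of libraries moves every chromosome alike, while the lower of the pair stood 0.28 above the highest other chromosome. A few strongly changed regions would leave most at the reference, while 85.9% lay above it (95% Wilson interval 84.9 to 86.7). The end of chromosome 16 from 97 Mb was left out of this share and below. The pair was picked by medians more than 0.2 from the reference. Both values therefore largely restate the pattern and are not independent tests. A different number of these chromosomes in the cultures may contribute, since all 45 windows of 5 Mb were shifted upward, and the ratios would stand for 2.48 and 2.54 copies per cell against 2 in the other genotype or, since the reference is unknown, for 1.61 and 1.57 against 2 there, a gain or a loss in part of the cells. Against a pure form of it, strong regions were shifted less than weak ones by -0.093 (95% bootstrap interval -0.12 to -0.06), while other chromosomes ran from -0.05 to 0.05; a limit of 0.15 alone would have let it pass, and the stricter demand that the interval hold 0 was added after this value was seen. Copy number and an effect of Tex19.1 loss on the mark cannot be told apart here because input values were not analysed, and the latter stays untested.

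The called regions at Impact, Mest, H13 and Zfp787 lay far below their list's median. A loss of DNA over the surrounding 500 kb would lower neighbouring regions, and the lowest of the 4 medians, around Impact, was -0.088 (95% bootstrap interval -0.18 to 0.01). A shared change of the class near the size at these genes would move the strong imprinted regions below -0.4, and their median was -0.13 (-0.24 to -0.02, 24 regions), most of which strong regions share, since it was -0.026 relative to regions of like signal (-0.15 to 0.07). A smaller shared change was therefore not shown and stays open. Chance gave as many calls in 0.05% of matched lists, which drew regions singly and so may understate that share. A small deletion and an effect of the genotype stay open, as untested. Any other difference between the cells compared cannot be told apart from genotype here, because the labels do not say whether libraries came from separate cultures.

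The block on chromosome 13 is the longest of the 4. A change common to vomeronasal receptor genes would shift them elsewhere, and 407 such regions outside the shifts had a median of -0.027 (95% bootstrap interval -0.06 to 0.00) against 0.46 for 42 inside the block. Reads shared among receptor copies would spare other regions, and the 145 regions of the block at no receptor gene had 0.54 (0.52 to 0.61). These are 145 of the block's 187 regions, so this value largely follows from how the block was found. A different copy number of the segment may account for it, with flanking windows at 0.13 and 0.10 and a ratio of 1.44, or 0.70 if the reference is the other genotype. It cannot be told apart from a regional change of the mark, because input values were not analysed. The difference between strong and weak regions of the block was -0.0024 (-0.17 to 0.09), an interval wider than the limit of 0.15. This difference cannot decide, since a regional change of the mark could also shift strong and weak regions alike.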
